A study of Mus musculus with 6 samples.

How the data were processed

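Primary acinar cells of the mouse pancreas, the exocrine cells that make and store digestive enzymes, were profiled in 6 libraries of strain C57BL/6J. The labels give 3 control libraries of wild-type genotype and 3 libraries of a conditional knock-out (cKO) of the estrogen-related receptor gamma, an orphan nuclear receptor encoded by Esrrg. Per the labels' protocols, the cells were held in Waymouth's medium with serum, a trypsin inhibitor, antibiotics and epidermal growth factor, and RNA was taken with Trizol. Libraries were made from 500 ng of total RNA with a Lexogen QuantSeq kit, which primes on poly(A) tails and reads 1 tag near the 3' end of each transcript. The time in culture, the way the gene was deleted, the part deleted, the purity of the cells and the age and sex of the animals are not given in the sources used here. The labels number the libraries 1 to 3 in each group and do not say whether these came from separate animals. The p-values of single genes therefore measure the spread between these libraries, which may be technical.

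The authors deposited raw counts of reads per gene symbol, 1 table per library, with no normalization. Bowtie2, edgeR and the builds mm10 and GRCm38 are named in the submitters' processing notes, with no version and no role. The counting tool, the annotation, the strand setting, the treatment of reads that match several places and any filter are not given in the sources used here. Several consequences follow for the values. A 3' tag count depends little on transcript length but does depend on the annotated 3' end. Genes with near-identical copies can share, lose or gain reads: Gapdh, which has many processed pseudogenes, was counted at 29, 47 and 25 reads in the control libraries. Overlapping genes on opposite strands cannot be told apart unless the counting used the strand. No molecular identifiers are described, so PCR copies are counted, and all intervals and floors below cover counting error only.

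Each table held 23282 rows with 23237 distinct symbols. Of these, 36 symbols stood on more than 1 row, on 81 rows in all, which were kept as separate rows. Symbols were at most 12 characters long, and longer names had been shortened to that length. Of the symbols, 22130 matched 1 gene of the GENCODE M21 annotation of GRCm38, from which coordinates, exon lengths and GC content were taken. Genes of the mitochondrial genome were not analysed here, so the planned share of counts from them was left out, as was the list of those genes.

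Library totals ran from 15.2 M to 25.2 M counts (M, mega). A count of 0 allows up to 0.119 to 0.198 CPM of the library total (3 counts). The share of counts in digestive enzyme genes carries an exact Clopper-Pearson 95% interval per library and was compared between groups with an exact 2-sided permutation test, which cannot go below 0.1 with 3 libraries against 3.

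Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest). Genes were kept with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15) and libraries were scaled with TMM factors. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are given as CPM (counts per M counts) of the effective, TMM-scaled library size, as mean ± SD over 3 libraries. Log2 CPM used a prior count of 2. The TMM scale sets the bulk of genes to no change. It differs from a scale of library totals, and both are given where the difference matters.

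Before the data were examined, 30 gene lists were fixed to suit acinar cells, a nuclear receptor known for mitochondrial genes, and other cell types that an acinar preparation could hold. Each list with at least 5 tested members was compared with all other tested genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 29 lists. The test was repeated with the correlation estimated from the 6 libraries, and with fry. The rule for named genes, also fixed before, takes 4 sets. They are Esrrg, Esrra, Esrrb and Ppargc1a; the 12 largest rises and 12 largest falls past the threshold among named genes with non-overlapping groups and a mean log2 CPM of at least 3; up to 4 members per list with the smallest p (the 2 most abundant for cell type markers); and Ins2, Gcg, Krt19, Col1a1 and Ptprc as signs of purity. Unnamed gene models, pseudogenes and segments of immunoglobulin or T cell receptor genes were skipped. A few further list members are printed to show the range or the exceptions of a list, and these, like Casp9, Casp8, Rn45s and Gapdh, were chosen after their values were seen. Single values of a few list members are not reported here.

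The edgeR fit was tested on simulated data drawn from the control means and the dispersions of these libraries. With 11865 genes tested and no change in composition, 46.0% of 2-fold changes and 92.9% of 4-fold changes were called, and 0.129% of unchanged genes. With the digestive enzyme genes lowered 16-fold as well, 11706 genes were tested, 52.0% and 92.9% were called, and 0.0871% of unchanged genes. Few other genes were changed, in random directions (100 by 2-fold and 98 by 4-fold in the first simulation). Most genes were thus unchanged by design, as TMM scaling assumes. In the real libraries 5868 of 13132 tested genes were called, so these rates need not hold there.

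Before the data were examined, these other settings were chosen: RLE and upper-quartile factors, scaling without the 50 most abundant genes, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 10 CPM in 3 libraries, the replicate number as a block, a test against a fold of 1.5 (glmTreat), and leaving out each library in turn. Settings added after the data were seen were the enzyme list with Amy2a2, Amy2a3, Amy2a4, 2210010C04Ri and Spink1, a denominator without Rn45s, a fit without Rn45s, Casp9 and the enzyme list, and libraries thinned to the smallest effective size.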

Results

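The transcriptome of primary pancreatic acinar cells was measured by 3' tag sequencing in 3 control and 3 ERRγ cKO libraries, to ask which genes the knock-out changes. ERRγ is a nuclear receptor known as a regulator of mitochondrial genes. The control libraries held 24.4 M, 25.2 M and 23.0 M counts and the cKO libraries 15.2 M, 17.0 M and 16.4 M. More genes had at least 1 count in cKO (15999.7 ± 524, SD, n = 3) than in control (13647 ± 95.5, SD, n = 3). Though the cKO totals were lower, their counts outside the digestive enzyme genes described below, Rn45s and Casp9 were higher. These averaged 9.28 M per cKO library and 1.82 M per control library. The remaining genes were thus sampled more deeply in cKO, and the numbers of genes are not compared at equal depth. Replicates of 1 group differed by more than sampling noise in every pair, with a chi-square per degree of freedom between 13.3 and 412. The first principal component held 69.0% of the variance and parted the groups, with cKO replicate 2 at 56.4, nearer to the controls than cKO replicates 1 and 3 at 99.1 and 86.4.

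Esrrg lies on chromosome 1 (187608791 to 188214885, plus strand, GRCm38). It was counted 0 times in each control library, and 0, 9 and 1 times in cKO replicates 1, 2 and 3. Against the effective library sizes, the 9 counts were 0.271 CPM, which is under the 0.353 to 0.399 CPM that a count of 0 allows in the controls. A 3' tag can lie outside a deleted part, which the labels do not name, so these counts give no check of the genotype labels. The related receptor gene Esrrb had 0 counts in all 6 libraries, and Esrra did not pass the test (log2 fold change 0.13 ± 0.17, SE; adjusted p = 0.550). Ppargc1a, which encodes the ERR coactivator PGC-1α (chromosome 5, 51454250 to 51567726), fell by 3.67 ± 0.90 on the log2 TMM scale (adjusted p = 0.00427). It had 7, 26 and 12 counts in control and 0, 9 and 11 in cKO. These low raw counts overlap between the groups, so the size of the fall rests on the effective library sizes. Those averaged 7.96 M in control and 50.8 M in cKO. The fold change of Ppargc1a was -4.26 without cKO replicate 2 and -3.02 without cKO replicate 1.

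Digestive enzyme genes took a smaller share of the counts in the cKO libraries. The 33 listed genes in the tables, which include amylases, trypsins, elastases and lipases, made up 62.4% (95% interval 62.4 to 62.4), 60.3% (60.3 to 60.4) and 62.0% (62.0 to 62.0) of counts in the control libraries. In cKO replicates 1, 2 and 3 they made up 18.1% (18.0 to 18.1), 45.2% (45.2 to 45.2) and 24.0% (24.0 to 24.0). The group means were 61.6% ± 1.10 and 29.1% ± 14.3 (SD, n = 3 each), a difference of -32.5 percentage points, with every cKO library below every control library (exact 2-sided permutation p = 0.1, the smallest this design can give). With 5 genes added after the data were seen, 3 of them near-identical amylase copies, the means were 87.6% ± 0.415 and 35.3% ± 18.2, a difference of -52.4 points. The 45S pre-ribosomal RNA gene Rn45s took 2.14% ± 0.271 of control counts and 5.02% ± 1.60 of cKO counts (SD, n = 3 each; exact permutation p = 0.1). On the TMM scale its log2 fold change was -1.92 ± 0.66 (SE; edgeR adjusted p = 0.0276). That call was lost without any 1 control library or cKO replicate 3 (0.0848 to 0.146). The counts left beside these enzymes, Rn45s and Casp9 were 1.82 ± 0.0724 M per control library and 9.28 ± 2.71 M per cKO library (SD, n = 3 each).

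**Figure D1:**
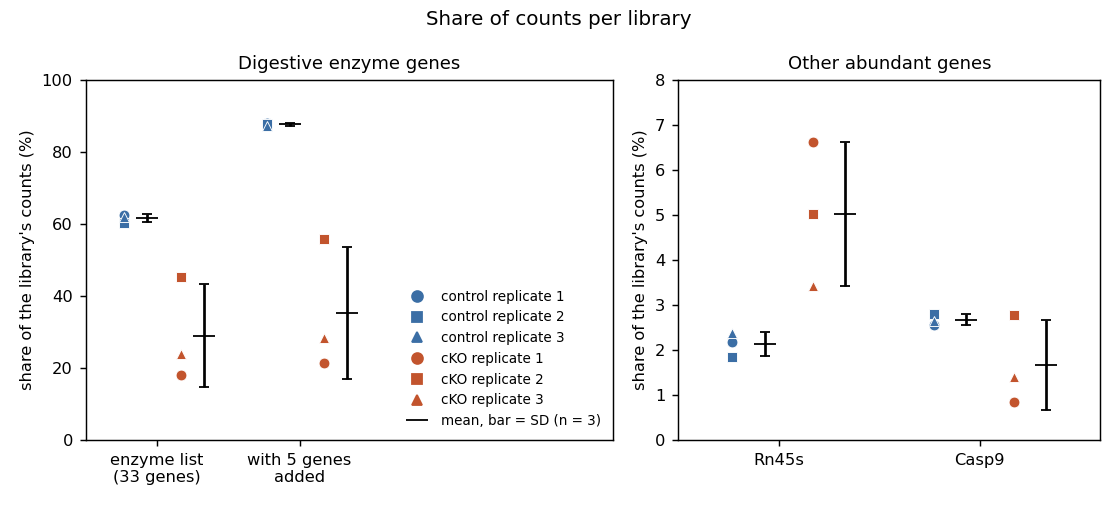
The vertical axes give the percent of each library's counts, the left panel for the 33 digestive enzyme genes and for that list with 5 genes added, the right panel for Rn45s and Casp9. Each point is 1 library, bars are mean and SD of 3 libraries, and cKO replicate 2 (45.2%) lies between the controls (60.3% to 62.4%) and cKO replicates 1 and 3 (18.1% and 24.0%).

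Because the enzymes filled most of the control libraries, the choice of scale sets the direction of most of the genes called lower. Fitted on library totals, log2 fold changes lie higher than on the TMM scale by a median of 3.26 (0.79 to 3.44), and the median of all tested genes is then 3.36 in place of 0.10. As a share of the whole library, 12992 of 13132 tested genes (98.9%) had a higher mean in cKO. Of the 2716 genes called lower, 139 had a lower share. Unless fitted on library totals, all fold changes, those above included, are therefore relative to the bulk of genes, and "rose" and "fell" are meant in that sense.

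On that scale 5868 of 13132 tested genes passed adjusted p 0.05 in edgeR, 3152 higher and 2716 lower in cKO, and 2540 and 1762 of these changed at least 2-fold. The groups did not overlap for 7375 genes (56.2%, where chance gives 10%). Among the 12 largest rises, Postn, a matrix protein of activated fibroblasts (chromosome 3, 54361109 to 54391037), rose by 5.31 ± 0.41 (log2, SE), from 0.602 ± 0.422 to 23.4 ± 8.03 CPM. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 4.71 ± 0.32. Ms4a7 (4.29 ± 0.90), Aif1 (4.13 ± 0.41), Ms4a6c (3.76 ± 0.71), Lst1 (3.64 ± 0.44) and Ly6c2 (3.80 ± 0.39) are expressed in monocytes and macrophages. The remaining large rises were Srpx (3.93 ± 0.30), the collagen gene Col6a5 (3.64 ± 0.25), the plasminogen activator gene Plat (3.62 ± 0.29), the hyaluronan-binding Tnfaip6 (3.59 ± 0.34) and the interferon-induced Ifi27l2a (3.53 ± 0.42). Adjusted p-values of these 12 genes ran from 4.71e-07 to 0.00937. Some had few counts in control replicates 1, 2 and 3: 8, 2 and 4 for Postn, 4, 6 and 5 for Ptgs2. Ms4a7 had 0, 3 and 15 and Lst1 had 3, 16 and 8. Such genes reached the mean log2 CPM of 3 through their cKO levels, and the sizes of their rises are uncertain. Leaving out 1 control library gave 5.98 for Postn and 4.46 for Ms4a6c (control replicate 1), 4.29 for Lst1 (control replicate 2) and 6.29 for Ms4a7 (control replicate 3). A further 170 tested genes had 0 counts in all control libraries, 166 of them among the calls, and no fold change is given for these. In all cKO libraries 0 tested genes had 0 counts. The effective sizes were larger there (50.8 M against 7.96 M on average), so these 2 numbers are not compared at equal depth.

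Among the 12 largest falls, Reg3a, Reg3d and Reg3b, which encode secreted lectins and lie side by side on chromosome 6 (78370657 to 78383827), had log2 fold changes of -6.76 ± 1.02, -5.76 ± 1.05 and -5.15 ± 0.54. Reg3b went from 6249 ± 654 to 176 ± 129 CPM. Hamp2, a hepcidin gene, had a fold change of -6.08 ± 0.72 and Dmbt1, a secreted scavenger receptor protein, of -5.43 ± 0.67. The pancreatic serpin gene Serpini2 (-5.91 ± 1.68), the cargo receptor gene Tmed11 (-5.70 ± 1.26) and Fam25c (-6.57 ± 1.87) stood closer to the threshold (adjusted p = 0.0489, 0.0233 and 0.0486). The amylase genes Amy2a2, Amy2a5, Amy2a3 and Amy2a4 (chromosome 3, 113247178 to 113356658) had fold changes between -5.08 and -5.07. Their near-identical sequences make the division of reads among them uncertain. Without cKO replicate 2 the fold changes were larger, at -8.26 for Reg3a, -7.33 for Reg3d, -5.91 for Reg3b, -6.99 for Hamp2, -6.63 for Dmbt1, -8.32 for Serpini2, -7.70 for Tmed11 and -6.37, -6.38, -6.39 and -6.40 for Amy2a2, Amy2a5, Amy2a3 and Amy2a4. Fam25c was -3.80 without control replicate 1 and lost its call without any 1 cKO library (adjusted p = 0.131 to 0.167), Serpini2 lost it without control replicate 2 or 3 or cKO replicate 1 or 3 (0.0526 to 0.142), and Tmed11 without cKO replicate 1 or 3 (0.0562 and 0.0715). With the replicate number as a block these 3 genes lost their calls (Fam25c 0.147, Serpini2 0.103, Tmed11 0.0660), and with no filter Fam25c (0.0642) and Serpini2 (0.0648) did. Fam25c also lost it in thinned libraries (0.0919), and both Fam25c (0.0690) and Serpini2 (0.0695) did in a test against a fold of 1.5.

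Of the 29 gene lists tested, 20 passed with camera, 9 higher and 11 lower in cKO than other genes. With the correlation between genes estimated from the 6 libraries, camera passed 0 lists after adjustment and 5 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed 23. The estimated correlation ran from -0.10 for adipocyte markers to 0.92 for digestive enzymes, with 0.43 for oxidative phosphorylation and 0.87 for cytosolic ribosome genes. At the preset of 0.01, camera p-values weigh a list against the spread across genes, not the spread between the 6 libraries.

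**Figure D2:**
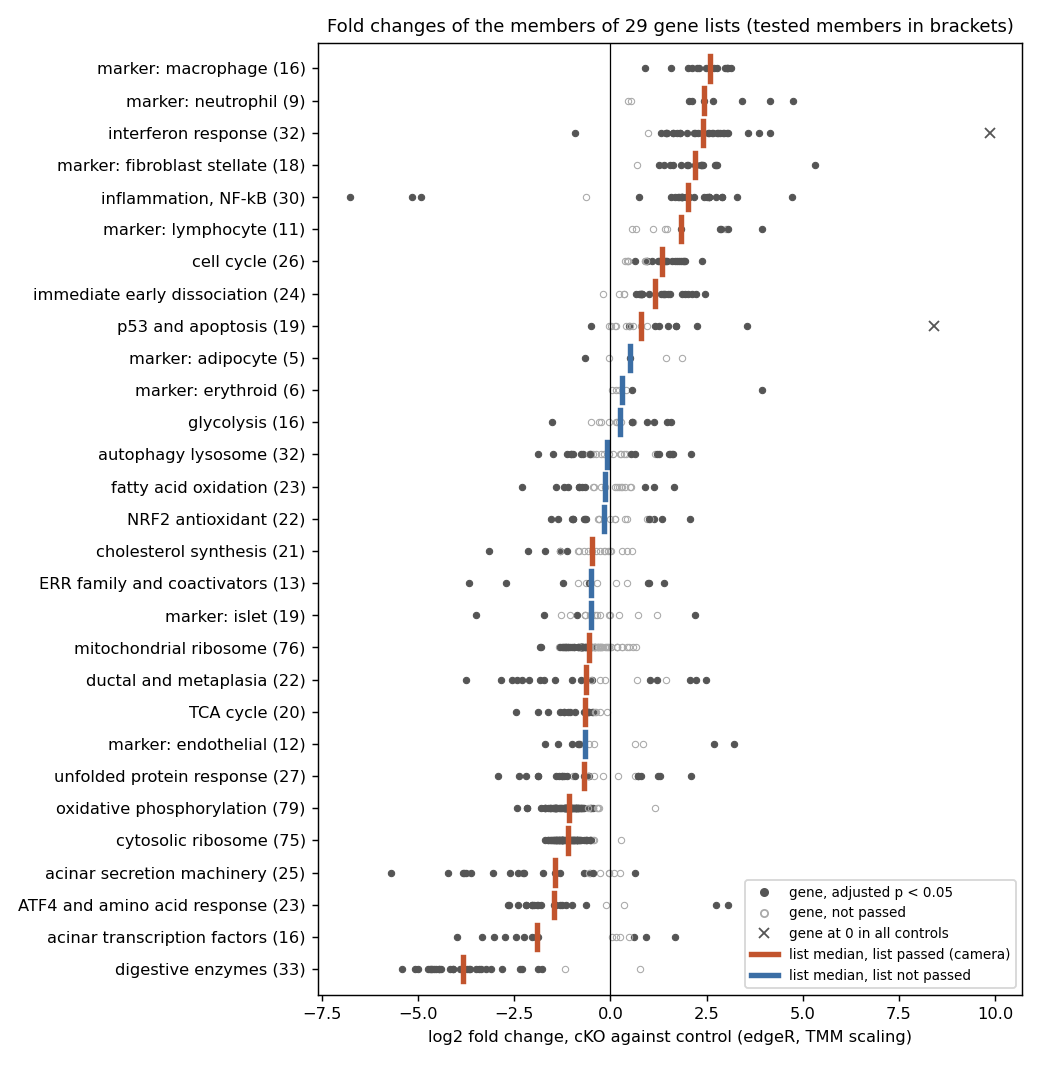
The horizontal axis gives the log2 fold change of cKO against control on the TMM scale, the vertical axis the 29 lists. Filled points are genes past adjusted p 0.05, open points are genes not past it, crosses are Mx1 and Eda2r, which had 0 counts in all controls so that their fitted values fix no size, and bars are list medians, from -3.83 for digestive enzymes to 2.60 for macrophage markers. Fitted on library totals, points lie to the right by a median of 3.26, which leaves the digestive enzyme median (-0.94) alone below 0.

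Acinar identity genes fell as a group. Among the digestive enzymes, 31 of 33 genes fell and 0 rose, with the same counts when adjusted over the list alone, and the median was -3.83 (camera adjusted p = 2.76e-14; adjusted p = 0.345 with an estimated correlation). The phospholipase gene Pla2g1b fell by 3.72 ± 0.43, Cela3a, an elastase gene, by 3.36 ± 0.51, and Sycn, which encodes a zymogen granule protein, by 3.64 ± 0.57. The trypsin genes Prss1 (-1.19) and Prss3 (0.77) did not pass, though Prss3 did without control replicate 1 (2.19; adjusted p = 0.00343). Without cKO replicate 2 the list median was -5.13, and the fold changes of Pla2g1b, Cela3a and Sycn were -4.33, -4.11 and -4.39.

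Of 16 tested transcription factors of acinar cells, 9 fell and 3 rose (4 rose and 9 fell when adjusted over the list alone), with a median of -1.91 (camera adjusted p = 0.0329; adjusted p = 0.375 with an estimated correlation). Those that fell included Xbp1, a regulator of the secretory pathway (-1.89 ± 0.20), Foxa3 (-2.46 ± 0.26), Spdef (-3.02 ± 0.45), and the acinar determinants Ptf1a (-2.25 ± 0.56), Rbpjl (-3.98 ± 0.77) and Bhlha15 (-3.33 ± 0.49). Rbpj, the widely expressed Notch pathway factor that is replaced by Rbpjl in mature acinar cells, rose by 1.68 ± 0.26, as did Tcf3 (0.93) and Gata6 (0.62). Without cKO replicate 2 the fold changes of Ptf1a, Rbpjl and Bhlha15 were -2.94, -4.96 and -4.01. Calls were lost by Ptf1a and Rbpjl without cKO replicate 3 (adjusted p = 0.0932 and 0.0586), by Tcf3 without control replicate 3 or cKO replicate 1 (0.0560 and 0.0545), and by Gata6 without control replicate 1 or 3 or cKO replicate 3 (0.0541 to 0.0856). The list did not pass among genes of at least 10 CPM in 3 libraries (adjusted p = 0.267).

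The machinery of regulated secretion fell in 18 of 25 genes and rose in 1, Snap23 (0.63), with the same counts when adjusted over the list alone (median -1.45; camera adjusted p = 1.05e-06; adjusted p = 0.299 with an estimated correlation). The granule proteins Rab3d (-2.24 ± 0.21) and Rab27b (-2.39 ± 0.27), the coat subunit Copz2 (-3.06 ± 0.26) and the muscarinic receptor Chrm3 (-2.61 ± 0.25) were among those that fell. Chrm3 and the cholecystokinin receptor gene Cckar (-3.84) encode the receptors through which acinar cells are told to secrete. Cckar was -5.06 without cKO replicate 2, and Snap23 lost its call without any 1 control library or cKO replicate 1 or 3 (adjusted p = 0.0568 to 0.104).

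The ductal and metaplasia list went both ways. Of 22 tested genes, 12 fell and 5 rose (6 rose and 12 fell when adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.0350; adjusted p = 0.370 with an estimated correlation). The mucin gene Muc1 (-3.74 ± 0.28; chromosome 3, 89229057 to 89233381) and the duct factor Sox9 (-1.82 ± 0.17) fell. The keratin genes Krt19 (1.03 ± 0.17) and Krt7 (1.20) rose, as did Cd44 (2.07 ± 0.19), Vim (2.22 ± 0.23) and Dclk1 (2.49, and 3.18 without control replicate 2). Vim and Cd44 are also expressed in fibroblasts and leukocytes, whose markers rose in the same libraries. The list did not pass among genes of at least 10 CPM in 3 libraries (adjusted p = 0.562) or in libraries thinned to 1 effective size (0.0799).

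Nuclear genes of the respiratory chain fell relative to other genes. In the oxidative phosphorylation list, 73 of 79 genes fell and 0 rose (75 and 0 when adjusted over the list alone), with a median of -1.08 (camera adjusted p = 4.66e-20; adjusted p = 0.299 with an estimated correlation). Ndufb8 (-1.62 ± 0.15), Ndufb9 (-2.17 ± 0.21) and Ndufa1 (-2.44 ± 0.23), subunits of complex I, and Uqcrfs1, the Rieske protein of complex III (-1.70 ± 0.17), had the smallest p-values. Ndufa1 went from 119 ± 14.3 to 22.0 ± 8.02 CPM. As a share of the whole library the list took 0.178% ± 0.00498 in control and 0.729% ± 0.166 in cKO, and 0 of its genes had a lower share in cKO.

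Among 20 tricarboxylic acid cycle genes, 16 fell and 0 rose (17 and 0 when adjusted over the list alone; median -0.65; camera adjusted p = 2.63e-06; adjusted p = 0.299 with an estimated correlation). The succinyl-CoA ligase subunits Suclg2 (-1.88 ± 0.20) and Suclg1 (-1.62 ± 0.22), Idh2 (-1.31 ± 0.15) and the pyruvate carboxylase gene Pcx (-2.46 ± 0.36) fell. Mitochondrial ribosome genes fell in 36 of 76 cases and rose in 0, also when adjusted over the list alone (median -0.56; camera adjusted p = 4.41e-07; adjusted p = 0.299 with an estimated correlation). Mrpl53 (-1.83 ± 0.17), Mrps21 (-1.80 ± 0.17), Mrpl30 (-1.31 ± 0.17) and Mrps24 (-1.27 ± 0.18) led that list.

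Other energy lists did not pass with camera. With fry, fatty acid oxidation (adjusted p = 0.0141), glycolysis (0.0330) and the list of the ERR family and its coactivators (0.0330) passed. Fatty acid oxidation had 3 genes that rose and 8 that fell of 23, also when adjusted over the list alone (median -0.13; camera adjusted p = 0.257), among them Hadh (-1.42 ± 0.17), the lipid-sensing receptor gene Ppara (-2.29 ± 0.39), the acylcarnitine carrier Slc25a20 (1.66 ± 0.32) and Acot2 (1.14 ± 0.22). In glycolysis 6 of 16 genes rose and 1, Aldoc (-1.52), fell, also when adjusted over the list alone (median 0.25; camera adjusted p = 0.257). The hexokinase genes Hk1 (1.58 ± 0.26) and Hk2 (1.13 ± 0.18), Pfkp (0.95 ± 0.21) and the lactate carrier Slc16a3 (1.48 ± 0.29) rose. Aldoc lost its call without control replicate 1 or 3 or cKO replicate 2 or 3 (adjusted p = 0.0567 to 0.181). The glycolysis list passed among genes of at least 10 CPM in 3 libraries (median 0.77; adjusted p = 0.0375). Of 13 tested genes of the ERR family and its coactivators, 3 rose and 4 fell, also when adjusted over the list alone (median -0.49; camera adjusted p = 0.229). Besides Ppargc1a, the corepressor-like receptor gene Nr0b2 (-2.73 ± 0.59, and -3.35 without cKO replicate 2) and Ppard (-1.24 ± 0.29) fell, and the coactivator gene Ncoa3 rose (1.40 ± 0.31).

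Cytosolic ribosome genes fell by a similar amount as respiratory chain genes, 72 of 75 with 0 that rose (74 and 0 when adjusted over the list alone), with a median of -1.11 (camera adjusted p = 9.08e-20; adjusted p = 0.345 with an estimated correlation). Rpl7a (-1.62 ± 0.16), Rpl29 (-1.53 ± 0.18), Rps2 (-1.53 ± 0.18) and Rps19 (-1.37 ± 0.17) had the smallest p-values. Many ribosomal protein genes have processed pseudogenes, so their absolute levels are uncertain. As a share of the library the list took 0.717% ± 0.0172 in control and 3.02% ± 0.538 in cKO.

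Genes of the unfolded protein response mostly fell, 15 of 27 against 6 that rose (16 and 7 when adjusted over the list alone; median -0.68; camera adjusted p = 0.0143; adjusted p = 0.528 with an estimated correlation). Edem1, which acts in the disposal of misfolded glycoproteins (-2.39 ± 0.24), the chaperone gene Dnajb11 (-1.88 ± 0.22) and Xbp1 fell. Ddit3, which encodes the stress-induced factor CHOP, rose by 2.08 ± 0.21. The list did not pass among genes of at least 10 CPM in 3 libraries (adjusted p = 0.227) or with fry (0.0673). In the ATF4 and amino acid list 19 of 23 genes fell and 2 rose, also when adjusted over the list alone (median -1.48; camera adjusted p = 2.63e-06; adjusted p = 0.345 with an estimated correlation). Those that fell included the amino acid carrier gene Slc7a5 (-2.05 ± 0.20), the folate enzyme gene Mthfd2 (-1.92 ± 0.19), Ddit4 (-2.20 ± 0.20) and the asparagine synthetase gene Asns (-2.66). The 2 that rose, the stress-induced cytokine gene Gdf15 (2.75 ± 0.23) and Trib3 (3.06), are known targets of CHOP as well.

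Cholesterol synthesis genes fell in 5 of 21 cases and rose in 0, also when adjusted over the list alone (median -0.49; camera adjusted p = 0.00458; adjusted p = 0.254 with an estimated correlation). Insig1, the sterol-regulated brake of the pathway (chromosome 5, 28071363 to 28078662), fell by 3.14 ± 0.24, and Fdps (-2.14 ± 0.30) and Sqle (-1.30 ± 0.30) also fell. Among genes of at least 10 CPM in 3 libraries the list's median was 0.0531 and it did not pass (adjusted p = 0.827).

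Inflammatory and interferon genes rose. In the inflammation and NF-κB list 26 of 30 genes rose and 3 fell, also when adjusted over the list alone (median 2.01; camera adjusted p = 4.41e-07; adjusted p = 0.254 with an estimated correlation). Nfkbiz (2.04 ± 0.17), the chemokine gene Cxcl16 (2.50 ± 0.23) and the complement gene C3 (2.44 ± 0.23) rose beside Ptgs2, and C3 went from 183 ± 25.0 to 992 ± 139 CPM. The 3 that fell were Reg3a, Reg3b and Reg3g, secreted by acinar cells. Interferon response genes rose in 30 of 32 cases and 1, Ifi27 (-0.92), fell, also when adjusted over the list alone (median 2.40, also with Mx1 at its lower bound; camera adjusted p = 5.62e-10; adjusted p = 0.299 with an estimated correlation). Ifit1 (2.94 ± 0.25), the immunoproteasome gene Psmb8 (2.65 ± 0.24), the peptide transporter gene Tap1 (2.42 ± 0.25) and B2m (2.38 ± 0.25) had the smallest p-values. Markers of macrophages rose in the same libraries.

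Immediate early and dissociation genes, which cells induce within a short time of stress or tissue digestion, rose in 20 of 24 cases and fell in 0 (21 and 0 when adjusted over the list alone; median 1.15; camera adjusted p = 2.93e-06; adjusted p = 0.254 with an estimated correlation). Klf4 (1.85 ± 0.17), Dusp1 (2.01 ± 0.18), Ier3 (2.11 ± 0.19) and Fosl2 (1.93 ± 0.19) rose, while Jun had a value of -0.21 that did not pass. Cell cycle genes rose in 18 of 26 cases and fell in 0 (19 and 0 when adjusted over the list alone; median 1.33; camera adjusted p = 9.29e-06; adjusted p = 0.345 with an estimated correlation), among them Top2a (1.88 ± 0.24), Birc5 (1.79 ± 0.28), Mki67 (1.60 ± 0.26) and Mcm3 (1.68 ± 0.28). Macrophage and fibroblast markers rose in the same libraries, and cKO replicate 2 had the lowest mean log2 CPM of the 3 cKO libraries for cell cycle genes (2.67) as for macrophage markers (5.29). That library was also the cKO library nearest to the controls for interferon (3.64), oxidative phosphorylation (4.70) and cytosolic ribosome genes (6.84). The match is thus not particular to macrophage markers. In the p53 and apoptosis list 9 of 19 genes rose and 1, Plk2 (-0.52), fell, also when adjusted over the list alone (median 0.80, also with Eda2r at its lower bound; camera adjusted p = 0.0109; adjusted p = 0.254 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a (1.49 ± 0.17) and the pro-apoptotic genes Bcl2l11 (1.71 ± 0.27) and Pmaip1 (3.55 ± 0.56, and 4.14 without control replicate 3) rose. Plk2 lost its call without control replicate 1 or 2 or cKO replicate 2 or 3 (adjusted p = 0.0799 to 0.216). The p53 list did not pass among genes of at least 10 CPM in 3 libraries (adjusted p = 0.177).

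Autophagy and lysosome genes went both ways, with 9 of 32 that rose and 9 that fell (11 and 10 when adjusted over the list alone), and the list did not pass (median -0.10, mean 0.0671; camera adjusted p = 0.436). The lysosomal genes Npc2 (1.56 ± 0.19) and Ctsb (1.53 ± 0.20) rose, and Ulk1 (-1.88 ± 0.19) and Gabarapl2 (-1.49 ± 0.19), which act in forming autophagosomes, fell. In the NRF2 antioxidant list 4 of 22 genes rose and 8 fell, also when adjusted over the list alone (median -0.16; camera adjusted p = 0.412). Nfe2l2 (1.35 ± 0.17) and Srxn1 (1.12 ± 0.19) rose, and Gstm2 (-1.54 ± 0.22) and Sod2 (-0.97 ± 0.17) fell.

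Markers of other cell types moved apart. Fibroblast and stellate cell markers rose in 17 of 18 cases and fell in 0, also when adjusted over the list alone (median 2.21; camera adjusted p = 2.68e-09; adjusted p = 0.299 with an estimated correlation). The collagen genes Col1a1 (2.73 ± 0.22), Col1a2 (2.37 ± 0.26) and Col3a1 (2.71 ± 0.25) rose, Col1a2 from 284 ± 14.7 to 1464 ± 340 CPM. All 16 macrophage markers rose, also when adjusted over the list alone (median 2.60; camera adjusted p = 3.12e-07; adjusted p = 0.345 with an estimated correlation). Cd74 rose by 3.02 ± 0.24 and the complement gene C1qb by 3.13 ± 0.23, and the leukocyte gene Ptprc by 2.78 ± 0.56. Neutrophil markers rose in 7 of 9 cases and fell in 0, also when adjusted over the list alone (median 2.44; camera adjusted p = 0.00198; adjusted p = 0.254 with an estimated correlation), with S100a8 at 2.44 ± 0.32 and S100a9 at 2.05 ± 0.27. Lymphocyte markers rose in 5 of 11 cases and fell in 0 (6 and 0 when adjusted over the list alone; median 1.84, and 2.70 without control replicate 1; camera adjusted p = 0.00606; adjusted p = 0.345 with an estimated correlation), with Jchain at 3.05 ± 0.23 and Ccl5 at 2.85 ± 0.46.

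Islet, endothelial, adipocyte and red cell markers did not pass as lists with camera, and of these only adipocyte markers passed with fry (adjusted p = 0.0209). Of 19 islet markers, 1 rose and 3 fell, also when adjusted over the list alone (median -0.51; camera adjusted p = 0.0632). Ins2 (-0.05 ± 0.26), Ins1 (-0.29 ± 0.27) and Gcg (-0.67 ± 0.36) did not pass, and Ins2 stood at 323 ± 94.0 CPM in control and 312 ± 102 CPM in cKO. With the replicate number as a block Gcg passed (-0.75; adjusted p = 0.00609). The islet list passed without cKO replicate 2 (median -0.78; adjusted p = 0.0109) or 3 (-0.52; 0.0299). Of 12 endothelial markers, 2 rose and 5 fell (3 and 5 when adjusted over the list alone; median -0.67, mean -0.01; camera adjusted p = 0.150), and the list passed without cKO replicate 2 (-0.79; 0.0482). Plvap had a value of -0.86 ± 0.21 (adjusted p = 0.00365) and Esam of 0.63 ± 0.25 (adjusted p = 0.0517). Of 5 adipocyte markers, 1 rose (Lpl, 0.51 ± 0.16) and 1 fell (Fabp4, -0.66 ± 0.23), also when adjusted over the list alone (median 0.51; camera adjusted p = 0.491). Lpl lost its call without control replicate 2 or 3 or cKO replicate 1 or 3 (adjusted p = 0.0529 to 0.0901), and Fabp4 without control replicate 1 or 3 or cKO replicate 1 (0.0918 to 0.153) or among genes of at least 10 CPM in 3 libraries (0.129). Of 6 red cell markers, 2 rose and 0 fell, also when adjusted over the list alone (median 0.31; camera adjusted p = 0.308), and Hba-a1 (0.05 ± 0.26) and Hbb-bs (0.41 ± 0.22) did not pass. Esam passed without control replicate 3 (0.98) or cKO replicate 1 (0.73), with RLE factors (adjusted p = 0.0494), with no filter (0.0223), among genes of at least 10 CPM in 3 libraries (0.0151) and with the replicate block (0.0356). Hbb-bs passed without control replicate 1 (0.69) or among genes of at least 10 CPM in 3 libraries (0.62).

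**Figure D3:**
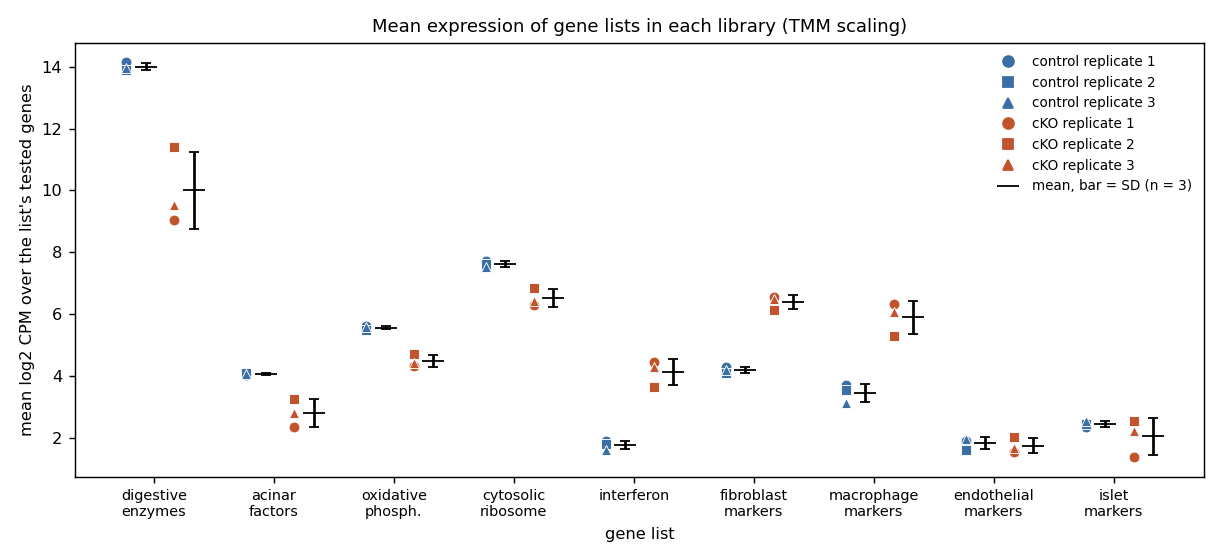
The vertical axis gives the mean log2 CPM (TMM scale) over the tested genes of 9 lists named on the horizontal axis, with 1 point per library and bars for mean and SD (n = 3). The groups do not overlap for the 7 lists on the left, cKO replicate 2 is the cKO library nearest to the controls in each of these 7, and the groups overlap for endothelial and islet markers. On the scale of library totals the cKO means lie higher against control, by 3.21 from the scaling factors, which are 3.92, 1.96 and 3.67 in cKO replicates 1, 2 and 3.

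Casp9, which encodes an initiator caspase of apoptosis, was among the most abundant genes in the tables, at 2.68% ± 0.120 of control counts and 1.67% ± 0.995 of cKO counts (SD, n = 3 each; exact permutation p = 0.3). Its fold change on the TMM scale was -3.60 ± 0.82 (adjusted p = 0.00226), beside -3.83 ± 0.95 for the elastase gene Cela2a. Without cKO replicate 2 these were -4.76 and -5.13. Casp9 (chromosome 4, 141793612 to 141815976, plus strand) and Cela2a (141814962 to 141826160, minus strand) overlap at their 3' ends, by 1015 bp of the gene spans, of which 94 bp are exon in both genes. Casp9 counts were 41.9% to 47.3% of Cela2a counts in the control libraries and 50.5% to 62.8% in the cKO libraries. Because the strand setting of the counting is not given in the sources used here, the Casp9 value is uncertain. The caspase gene Casp8 stood at 4.53 ± 0.415 CPM in control and rose by 1.25 ± 0.29.

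**Figure D4:**
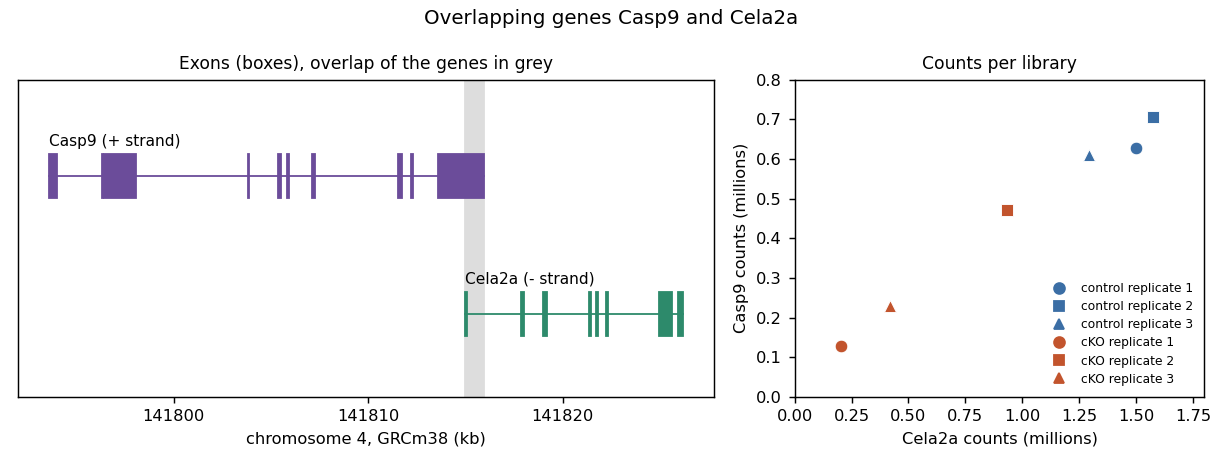
The left panel maps the exons of Casp9 and Cela2a on chromosome 4 (GRCm38, kb), with the 1015 bp overlap of the gene spans in grey. The right panel plots Casp9 counts against Cela2a counts in M, 1 point per library, and in all 6 libraries Casp9 has between 41.9% and 62.8% of the Cela2a counts.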

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

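The enzyme list with near-identical or renamed members, the denominator without Rn45s, the fit without the enzyme list, Rn45s and Casp9, and the thinned libraries were chosen after the data were seen. RLE factors, upper-quartile factors, scaling without the 50 most abundant genes, DESeq2, limma-voom and no filter gave 5352 to 5881 genes (DESeq2 left 2385 genes without an adjusted p), and thinning gave 5238. The fit without the 33 listed enzyme genes, Rn45s and Casp9, which kept the near-identical or renamed members, gave 5776. In none of these did a called gene change direction. Among genes of at least 10 CPM in 3 libraries, 4192 were tested and 2868 were called (1443 higher, 1425 lower), because fewer genes were tested, and 7 lists passed as lower. That filter moved log2 fold changes by a median of 0.22. A test against a fold of 1.5 called 3840 genes, 2175 higher and 1665 lower, as a stricter hypothesis does. Among named genes it ended the calls of Fam25c (adjusted p = 0.0690), Serpini2 (0.0695), Plvap (0.0964), Lpl (0.638) and Fabp4 (0.334). With the correlation estimated, camera passed 0 lists, 0 higher and 0 lower, by its construction a wider test. The enzyme share differed by -52.4 points with the near-identical or renamed members added, and by -32.4 points with Rn45s left out of the denominator.

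The replicate number as a block gave 5389 genes, 2884 higher and 2505 lower, with the same calls for all 29 lists. Among named genes the block ended the calls of Fam25c (adjusted p = 0.147), Serpini2 (0.103) and Tmed11 (0.0660) and gave calls to Gcg (0.00609) and Esam (0.0356). Same-numbered libraries did not deviate together (correlations across genes 0.0142, -0.0295 and -0.00774). No pairing by number was thus seen, though 3 libraries per group cannot exclude one. Leaving out 1 library gave 4464 to 6240 genes, 2388 to 3411 higher and 2076 to 2829 lower, 20 to 22 lists, and an enzyme share difference of -40.6 to -27.0 points.

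Fold changes of genes and medians of lists that turned in sign did so without passing a threshold, and the cause was not tested. They were Ins2 (0.16) and the lists of fatty acid oxidation (0.20), autophagy (0.01) and cholesterol synthesis (0.05) at 10 CPM in 3 libraries; fatty acid oxidation without control replicate 3 (0.01) or cKO replicate 2 (0.02); NRF2 without control replicate 2 (0.07) or cKO replicate 1 (0.02); Hba-a1 under the replicate block (-0.0094), without control replicate 2 (-6.0e-04) and without cKO replicate 2 (-0.28); Ins1 without control replicate 2 (0.010), against -0.56 without cKO replicate 2; and Ins2 without control replicate 2 (0.22) or cKO replicate 1 (0.18), against -0.29 without cKO replicate 2. Hba-a1 was 0.21 without cKO replicate 3. Alternatives for files of normalized values and for the share of mitochondrial genome counts were not run. DESeq2, limma-voom, upper-quartile factors, no filter and the test against a fold were run for genes and not for lists. Simulated 2-fold changes were called in 46.0% of cases.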

Other observations

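The 12 gene lists of the next paragraph and the paragraph after it, and the tests on enzyme genes, on markers of other cells, on cell mixture and on Casp9 were chosen after the results were seen; the splits of the libraries, the matching on length and GC content and the comparison of scalings were chosen before.

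All 9 tested MHC class II genes rose (median 3.28; camera adjusted p = 6.14e-05; adjusted p = 0.178 with an estimated correlation), H2-Aa from 20.3 ± 6.96 to 208 ± 79.1 CPM. Of 25 genes of matrix proteases, protease inhibitors and lysyl oxidases, 21 rose (median 1.99; camera adjusted p = 1.19e-08; adjusted p = 0.178 with an estimated correlation), with Mmp2 at 3.42 ± 0.33 (4.03 without control replicate 2). Dendritic cell markers rose in 7 of 9 cases (median 2.47; camera adjusted p = 0.00311; adjusted p = 0.178 with an estimated correlation) and mesothelial markers in 8 of 8 (median 2.10; camera adjusted p = 6.56e-05; adjusted p = 0.142 with an estimated correlation), with Msln at 2.01 ± 0.27, while mast cell markers did not pass (3 of 6 rose, 1 fell; camera adjusted p = 0.485) and Schwann cell markers had 3 tested members, too few for the test. Actin cytoskeleton genes rose in 18 of 26 cases and fell in 1 (median 0.96; camera adjusted p = 3.52e-04; adjusted p = 0.297 with an estimated correlation), with Actb at 1.21 ± 0.27.

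In the list of endoplasmic reticulum translocation and glycosylation 27 of 30 genes fell (median -1.25; camera adjusted p = 5.93e-10; adjusted p = 0.237 with an estimated correlation), with Ssr4 at -2.39 ± 0.30. Translation factor genes fell in 20 of 33 cases (median -0.75; camera adjusted p = 1.33e-06; adjusted p = 0.237 with an estimated correlation), with Eef2 at -1.55 ± 0.26, and transfer RNA synthetase genes in 11 of 20, against 1 that rose (median -0.57; camera adjusted p = 6.21e-04; adjusted p = 0.237 with an estimated correlation). Amino acid and one-carbon enzyme genes fell in 13 of 17 cases and rose in 2 (median -2.20; camera adjusted p = 3.25e-05; adjusted p = 0.178 with an estimated correlation), with Gnmt at -3.93 ± 0.58 (-4.72 without cKO replicate 2) and Gatm at -2.93 ± 0.23. Proteasome genes did not pass (6 of 31 fell, 1 rose; median -0.11; camera adjusted p = 0.0504). The class II list shares Cd74 with the macrophage markers, the protease list shares 4 genes with other lists, the translocation list 4, the amino acid list 2 and the mesothelial list 1.

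The real split of the 6 libraries gave 5868 genes and the highest of the other 9 splits gave 0 in edgeR (194 at an unadjusted p under 0.05), so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

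The cKO libraries held less digestive enzyme RNA and more RNA of macrophage and fibroblast markers. A lower share of acinar cells may contribute. Alone, it would lower all enzymes by about 1 factor. Relative to the list's own mean (limma), 22 of 33 enzyme genes changed. They included Prss3 and Prss1 (5.23 and 2.53 relative to the list), whose fold changes of 0.77 and -1.19 did not pass in edgeR. Among enzyme genes that passed in edgeR, falls ran from -1.79 for Pnliprp1 to -5.43 for Dmbt1. These were -2.44 and -6.63 without cKO replicate 2. Pnliprp1 lost its call without any 1 control library or cKO replicate 3 (adjusted p = 0.0646 to 0.0875). This test assumes that each enzyme's reads are its own and come from acinar cells only. Neither was tested, so the unequal falls do not exclude a loss of acinar cells. A lower acinar share alone would also raise markers of all other cell types alike. The gap between macrophage and islet markers instead moved by 2.82 on the log2 scale (3.44 pooled SD, with no overlap of the groups). Against endothelial and red cell markers the gap moved by 2.50 and 1.72, and against fibroblast markers by 0.23 (0.75 pooled SD, with overlapping groups). Markers of other cells thus did not all rise alike. The lists were paired after their medians were seen, so these gaps restate the medians. They do not decide whether a lower acinar share was the whole cause of the macrophage rise. More immune and stromal cells in the cKO tissue or preparation stay open: macrophage markers had a median of 2.60, with Cd74 at 25.0 ± 4.08 and 202 ± 60.4 CPM, and since libraries of equal content were not analysed here this cannot be told apart from a change within cells. All 16 macrophage and all 18 fibroblast markers were counted in all 3 control libraries too, 1 marker of each list is held by another list, and an effect of the missing receptor within acinar cells stays open and untested.

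Respiratory chain and cytosolic ribosome genes fell together, which could follow from features of short, abundant transcripts. Random genes matched on exon length, GC content and expression had a median of -0.40. The oxidative phosphorylation list lay 0.68 below it (difference -0.68, lower than all 10000 matched lists). The ribosome list lay at -0.53 from its matched genes, whose median was -0.58 (percentile 0.52). Matched genes thus fell too, by less than the lists. They were drawn singly, while list members were correlated (0.43 and 0.87). The percentiles therefore do not measure the spread between libraries and set no limit on the part of these features. Relative to all tested genes the higher of the 2 list medians was -1.18, a difference that no scaling factor can move, so it holds only for the fall relative to other genes. As a share of the library both lists were higher in cKO, and their absolute amount stays open. Another mixture of cells cannot be told apart from a change within acinar cells, since fibroblast markers (median 2.21) and macrophage markers do not overlap between the groups. A loss of ERRγ activity at mitochondrial genes is a hypothesis that the design names and these libraries leave untested.

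The Casp9 signal may be reads of Cela2a. Its fold change lies 0.23 from that of Cela2a (difference 0.233), and the last exon of Cela2a, of 94 bp, lies within the last exon of Casp9 on the opposite strand, where unstranded counting of 3' tags could place reads on either gene. Casp9 counts as a percent of Cela2a counts were 44.7 ± 2.70 in control and 56.0 ± 6.26 in cKO (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), so the ratio was not constant, and a change in Casp9 itself cannot be read from these counts.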
